A study of Mus musculus with 58 samples.

How the data were processed

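Bulk RNA sequencing of mouse somatosensory cortex was analysed in 58 libraries from C57BL/6J mice of both sexes. Per the labels, RNA was isolated with a Qiagen kit, polyadenylated RNA was selected, and directional NEBNext Ultra II libraries were prepared. Mice received 5 once-daily closed head injuries (5xCHI) or sham injuries at an age of 2 to 4 months. The p38 MAPK inhibitor SB239063 (SB, 20 mg/kg, intraperitoneal) or its saline vehicle was injected 30 min after each injury or sham procedure. The samples belong to the chronic time, about 1 month after the last injury, and the design text names about 18 and 34 days without saying which animal belongs to which day. Samples taken at the acute time were not analysed here. Each label describes a separate sample of its group, and the libraries were treated as separate animals. If any shared an animal, the p-values would measure a spread that is partly technical.

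The deposited values are raw read counts per gene, in 1 table of 9636 genes by 58 libraries. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used with GRCm39/mm39. Their versions, settings and annotation are not given in the sources used here, and neither is the strand setting, so overlapping genes and near-identical copies could share counts. The smallest count in the table is 101 and the smallest mean count of a gene is 270.1. Genes of low count were therefore left out before deposit by a rule that is not given in the sources used here. This limits what the table can show: Aif1, Cd68, Il1b, Tnf, Xist, Ddx3y and the mitochondrially encoded genes were not analysed here. Whether that rule explains the absence of mitochondrially encoded genes, which are abundant in brain, was not tested. The totals of 28316280 to 49158277 counts per library cover the listed genes and are not the full depth of sequencing. At these counts the spread between animals outweighs counting error (biological coefficient of variation 0.123, common dispersion 0.0152).

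Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM normalization and the quasi-likelihood test with robust estimation. The model held 8 groups (sex by injury by treatment) and the cohort, of which the labels give 4 in each sex, as a fixed effect within sex. It had 14 coefficients and 44 residual degrees of freedom. The filterByExpr filter removed no gene. Comparisons over both sexes are the mean of the female and the male difference. They were injury in vehicle mice, SB in injured mice, injured SB against sham vehicle, SB in sham mice, the injury by SB interaction, injury and SB in each sex, and the sex difference of both effects. All tests were two-sided and were adjusted by Benjamini-Hochberg at 0.05 over the 9636 genes. Fold changes are log2 values with standard errors (SE), levels are TMM-scaled CPM values with standard deviations (SD), and intervals are at 95%. No library pair of a group came close to sampling noise (lowest chi-square per degree of freedom 9.83), so each was counted as a sample of its own.

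Lists of 34 gene groups were written before the data were examined, and 27 with at least 3 measured genes were tested with camera of limma 3.58.1, with its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within each comparison. They cover microglia, astrocytes, immune responses, the p38 pathway, immediate early genes, the oligodendrocyte lineage, neurons, cortical layers, vessels, neighbouring brain regions, oxidative phosphorylation, ribosomal proteins, heat shock, the clock, the glucocorticoid response and cholesterol synthesis. The other 7 were not tested: meningeal fibroblast and peripheral leukocyte genes had 1 measured member each, and choroid plexus, red blood cell, border macrophage, mitochondrially encoded and sex check genes had 0. Several lists were measured only in part: 6 of 29 cytokine and NF-kB, 6 of 27 interferon response and 5 of 16 complement genes. The same holds for 6 of 23 reactive astrocyte, 3 of 16 antigen presentation and 11 of 22 disease-associated microglia genes. A result for such a list covers its measured members only. Complement C4b stands in both the reactive astrocyte and the complement list. After the list results had been seen, the mean log2 CPM of each list (prior count 2) was also tested by permuting labels within cohorts, exactly within each sex and with 100000 draws over both. With the preset correlation, other splits of the samples within cohorts also called lists, so such a call alone is weak evidence.

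The genes named were set by a rule written before the data were examined. For injury in vehicle mice and SB in injured mice it takes up to 12 passing genes per direction or, with none passing, the 5 of smallest p in each direction. The other comparisons take 5 per direction or, with none passing, 2. The rule adds up to 4 members of each list that passed in the direction of the list, up to 2 members of any other list described, and Mapk14, Mapk11, Mapkapk2, Gfap and the 6 genes listed above as not analysed, leaving out predicted genes without a name. Some genes that the rule takes are not reported here. A gene outside the rule is marked where it appears.

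The alternatives chosen before the data were examined were no cohort term, a replicate block in place of the cohort, size factors in place of TMM, DESeq2 1.42.0, no filter, a mean CPM of at least 1, 2 surrogate variables (sva 3.50.0), each sex alone, the estimated correlation, and each library of the groups of 2 to 5 left out in turn. Chosen after seeing the data were the removal of 4 libraries far from the rest on a principal component, limma voom with quality weights, the myelin level as a term, the slope over transcript length as a term and each library of the larger groups left out in turn. Lengths and GC contents came from GENCODE annotation of another mouse build (GRCm38), matched by symbol for 9549 genes (99.1%), and no coordinates were taken from it. Up to 100 splits of the samples within cohorts, the real one among them, were fitted for each comparison.

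The gene test was tested on simulated counts of the 9636 genes with 200 changed. For injury in vehicle mice it recovered 80.6% of the genes changed 1.2-fold and 100% of those changed 1.5-fold. For SB in injured mice these shares were 76.1% and 98.5%, for injured SB against sham vehicle 79.1% and 98.5%, for SB in sham mice 32.8% and 95.5%, and for the interaction 17.9% and 86.6%. Simulated genes vary independently of each other, which the genes of these libraries do not, so the shares describe the test on such data alone. The permutation of list scores called 4 of 100 unchanged lists and returned 0.522 for a shift of 0.5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.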

Results

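Gene expression was measured by RNA sequencing in the somatosensory cortex of 58 mice, about 1 month after 5 daily closed head injuries (5xCHI) or sham injuries. Each injury or sham procedure was followed by an injection of SB239063 (SB), an inhibitor of the stress-activated kinase p38 MAPK, or of saline vehicle. The females comprised 11 injured SB, 12 injured vehicle, 3 sham SB and 9 sham vehicle mice. The males comprised 8 injured SB, 8 injured vehicle, 2 sham SB and 5 sham vehicle mice. Mice came from 4 cohorts per sex, each with injured SB, injured vehicle and sham vehicle mice, whereas sham SB mice were found in 2 cohorts of each sex. Library totals over the 9636 listed genes ran from 28316280 to 49158277 counts, and group means lay between 35500000 ± 5280000 (SD, n = 8) in injured vehicle males and 42500000 ± 4020000 (SD, n = 2) in sham SB males.

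Of the labelled factors, the cohort had the largest share of the first principal component. The first principal component held 27.5% of the variance, of which 57.1% followed the cohort and 5.97% the condition beyond it. No chance level was computed for these or later shares of a component, so small ones may be chance. The fourth component, 9.31% of the variance, carried the myelin genes Mobp, Mbp and Mal at one end and followed the cohort for 35.3% and the condition beyond it for 15.9%. The X-linked genes Kdm6a, Eif2s3x and Kdm5c were higher in the 35 females than in the 23 males by 0.35, 0.44 and 0.42 (log2 CPM), and on their mean 2 females lay below the highest male.

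In vehicle mice, injury was compared with sham to find which transcripts still differed a month after repeated head injury. Glucocorticoid response genes fell: all 10 measured members were lower in injured mice, with a mean log2 fold change of -0.18 (adjusted p = 3.2e-09 by camera). Their leading members were Sgk1, a kinase induced by glucocorticoids, at -0.44 ± 0.15 (SE), Ddit4, an inhibitor of mTOR signalling, at -0.26 ± 0.12, the cell cycle inhibitor Cdkn1a at -0.25 ± 0.079, and Tsc22d3, the glucocorticoid-induced leucine zipper gene, at -0.24 ± 0.077. Sgk1 stood at 75.5 ± 26.9 CPM (SD, n = 20) in injured vehicle mice and at 102 ± 42.5 CPM (SD, n = 14) in sham vehicle mice. The list kept its call with an estimated correlation (adjusted p = 0.0193), and 3 of its genes passed when adjusted over the list alone, against 0 over all genes.

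Glial and immune lists moved by smaller amounts. Homeostatic microglia genes rose, all 10 being higher (mean 0.069, adjusted p = 0.00108), with Csf1r, the receptor that maintains microglia, at 0.086 ± 0.053 and the chemokine receptor gene Cx3cr1 at 0.083 ± 0.055. Reactive astrocyte genes rose (4 of 6 higher, mean 0.10, adjusted p = 0.0158), led by the intermediate filament gene Gfap at 0.22 ± 0.097 (unadjusted p = 0.0302, adjusted p = 1 by edgeR) and complement C4b at 0.16 ± 0.14. Gfap stood at 184 ± 34.0 CPM (SD, n = 20) in injured and 158 ± 42.9 CPM (SD, n = 14) in sham vehicle mice. With an estimated correlation neither list passed (adjusted p = 0.34 for both). Myelin genes rose, 15 of 15 higher (mean 0.072, adjusted p = 0.0115; adjusted p = 0.659 with an estimated correlation), with Aspa, which encodes aspartoacylase, at 0.18 ± 0.13. The rise was seen in males only: the mean log2 CPM of the list differed by 0.33 in males and by -0.095 in females. These values depended on single libraries. Without 4 libraries far from the rest on a principal component, a check chosen after seeing the data, neither sex alone had a myelin call. The list was then at 0.12 in males (adjusted p = 0.0671 by camera) and at -0.028 in females (adjusted p = 0.835). Over both sexes permutation within cohorts gave p = 0.49 for the myelin list. Antigen presentation genes fell, with all 3 lower (mean -0.10, adjusted p = 0.0248; adjusted p = 0.145 with an estimated correlation), among them the transporter gene Tap2 at -0.17 ± 0.091 and B2m at -0.10 ± 0.072.

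Activity and housekeeping lists were lower. Immediate early genes, which neuronal activity induces, fell (12 of 14 lower, mean -0.14, adjusted p = 3.73e-04), with the growth factor gene Bdnf at -0.20 ± 0.086 and the transcription factor gene Egr3 at -0.18 ± 0.073. The fall came from males, as 9 of the 14 were higher in injured females, and the mean ran from -0.23 to -0.064 with a male sham vehicle library left out (replicate 4 or 2). Oxidative phosphorylation genes fell, 19 of 19 lower (mean -0.098, adjusted p = 1.46e-08), with the complex I gene Ndufs5 at -0.15 ± 0.067 and Cox7c at -0.12 ± 0.060. Cytosolic ribosomal protein genes fell, 24 of 24 lower (mean -0.063, adjusted p = 8.33e-05), including Rps3 at -0.090 ± 0.057. Heat shock genes fell (9 of 10 lower, mean -0.050, adjusted p = 0.00947), with the chaperone gene Hspa5 at -0.12 ± 0.060. With an estimated correlation these 4 calls were lost, at adjusted p = 0.355, 0.34, 0.577 and 0.355. Across 9549 genes, which are not independent replicates, the injury fold change followed transcript length (Spearman rho 0.491), and oxidative phosphorylation and ribosomal genes have short transcripts.

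No single gene passed for injury. By edgeR 0 of 9636 genes had an adjusted p under 0.05, the smallest being 1, and 169 had an unadjusted p under 0.05, where 481.8 would be reached by chance among independent genes. DESeq2 gave 0 and 182. The genes of smallest p did not pass: Nfkbia, the inhibitor of NF-kB, at -0.27 ± 0.079 (unadjusted p = 0.00128), Lyrm1 at -0.20 ± 0.062, the ribosomal RNA processing gene Rrp36 at -0.16 ± 0.055, Cdkn1a and Tsc22d3, and, higher, the adaptor gene Gab2 at 0.15 ± 0.054, Fastkd1 at 0.14 ± 0.050, Eid2b at 0.14 ± 0.052, the nociceptin receptor gene Oprl1 at 0.11 ± 0.041 and the chromatin remodeller gene Chd8 at 0.091 ± 0.033. For 99.9% of genes the 95% interval of the fold change lay within 1.5-fold in either direction. The kinase genes Mapk14 (-0.041 ± 0.034) and Mapk11 (-0.12 ± 0.079) and their substrate gene Mapkapk2 (-0.051 ± 0.054) did not pass. The p38 pathway list was not called (adjusted p = 0.884, 9 of 17 higher).

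The other 17 lists without a call for injury had adjusted p from 0.0842 to 0.971. They were mural cell, deep cortical layers, excitatory neuron, cytokine and NF-kB (with Nfkbia past the threshold when adjusted over the list alone), cholesterol synthesis, hippocampus, interferon response, circadian clock, thalamus, complement, disease-associated microglia, oligodendrocyte precursor, upper cortical layers, endothelial cell, striatum, astrocyte and inhibitory neuron genes. Few cytokine and NF-kB (6 of 29), interferon response (6 of 27) and complement genes (5 of 16) were measured. The absence of a call does not speak for unmeasured members such as Il1b and Tnf. Single male sham vehicle libraries ended several calls. Without replicate 5 the microglial list was at 0.049 (adjusted p = 0.0704) and the reactive astrocyte list at 0.072 (adjusted p = 0.313), and without replicate 2 the myelin list was at -0.012 (adjusted p = 0.999). Without replicate 4 the ribosomal list was at -0.018 (adjusted p = 0.802) and the heat shock list at -0.031 (adjusted p = 0.29). The antigen presentation list did not pass without replicate 3, 4 or 5 (adjusted p = 0.0737, 0.212 and 0.0532). Without 4 libraries that lay far from the rest on a principal component, a check chosen after seeing the data, the oxidative phosphorylation list was at 0.012 (adjusted p = 0.511) and the ribosomal list passed in the opposite direction at 0.035 (adjusted p = 6.17e-04). The immediate early (-0.051, adjusted p = 0.0527), myelin (0.046, adjusted p = 0.16) and antigen presentation lists (-0.053, adjusted p = 0.259) lost their calls there. With each of the 58 libraries left out in turn, the myelin call was lost in 8 cases, and the glucocorticoid list kept its call in all, between -0.20 and -0.14.

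**Figure D1:**
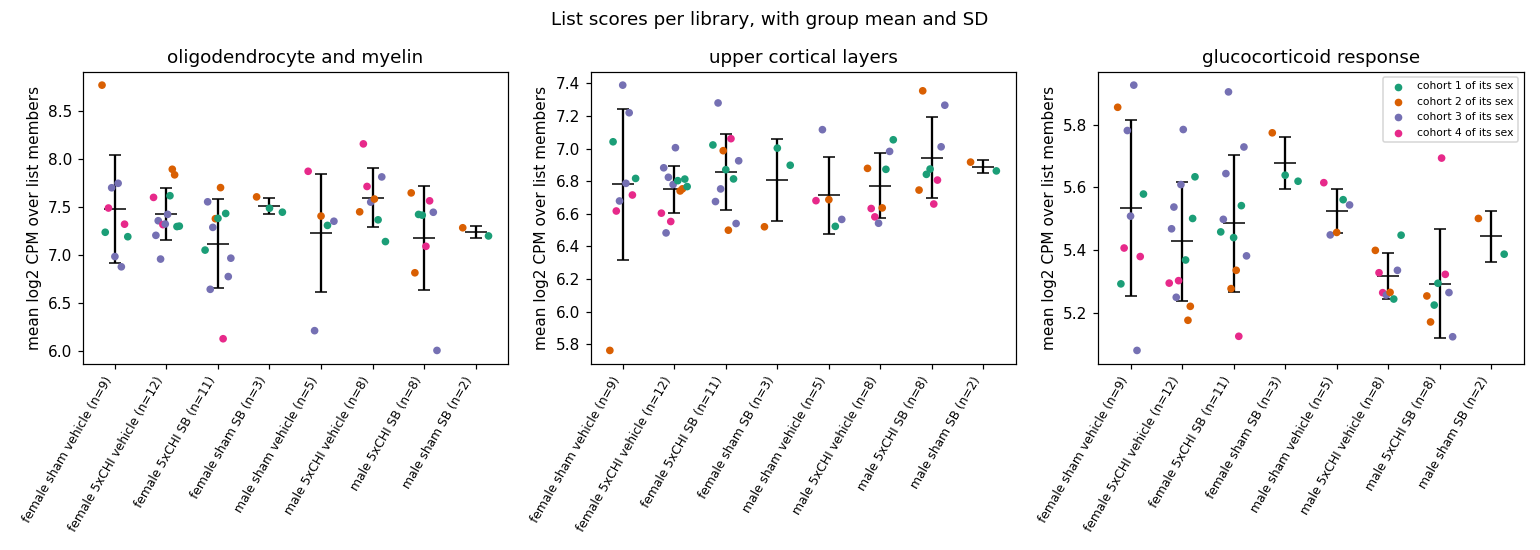
Mean log2 CPM of the oligodendrocyte and myelin, upper cortical layer and glucocorticoid response lists in each library, by group. Each point is a library coloured by cohort, and bars give the group mean and SD. Injured SB females stood at 7.12 ± 0.46 and injured vehicle females at 7.43 ± 0.27 for the myelin list, and 1 female sham vehicle library lay at 8.77.

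Averaged within cohorts, the glucocorticoid response score of injured vehicle mice differed by -0.16 from that of sham mice and was higher in 1 of the 8 cohorts, the differences running from -0.66 to 0.065. A permutation test within cohorts, added after the list results were seen, gave p = 0.0132, or 0.237 after adjustment over the 27 lists. By this test no list passed for injury.

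In females alone, 6 lists passed for injury. Homeostatic microglia genes rose (10 of 10 higher, mean 0.10, adjusted p = 2.37e-04), including Tmem119 at 0.16 ± 0.078 and Cx3cr1 at 0.15 ± 0.067, as did reactive astrocyte genes (6 of 6, mean 0.13, adjusted p = 0.0292) with C4b at 0.36 ± 0.17. Glucocorticoid response (7 of 10 lower, mean -0.14, adjusted p = 0.00437, Sgk1 at -0.49 ± 0.19) and heat shock genes (9 of 10 lower, mean -0.073, adjusted p = 0.00437, Bag3 at -0.19 ± 0.085) fell. These 4 lists did not pass with an estimated correlation (adjusted p = 0.394 each). Myelin genes fell, with 15 of 15 lower (mean -0.14, adjusted p = 0.0356, Mobp at -0.23 ± 0.18), and so did oxidative phosphorylation genes (18 of 19 lower, mean -0.069, adjusted p = 0.0126), and both had adjusted p = 0.742 with an estimated correlation. For edgeR 0 genes passed, 303 had an unadjusted p under 0.05, and DESeq2 gave 0 and 311. Leading genes were the protocadherin gene Pcdh8 at 0.57 ± 0.13 (adjusted p = 0.453), Fxyd6 at 0.32 ± 0.083, Cdr2 at -0.56 ± 0.15 and the insulin-degrading enzyme gene Ide at -0.47 ± 0.12. Without the 4 far libraries, 2 of them female sham vehicle mice, none of the 6 lists kept its call in the same direction, the oxidative phosphorylation list passed in the opposite one (0.085, adjusted p = 0.0416), and the myelin list was at -0.028 (adjusted p = 0.835). Leaving out female sham vehicle replicate 1 alone put the glucocorticoid list at -0.064 (adjusted p = 0.386) and the myelin list at -5.2e-04 (adjusted p = 0.855).

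In males alone, immediate early genes fell, 14 of 14 lower (mean -0.36, adjusted p = 1.02e-05), with Egr4 at -0.79 ± 0.28 and Egr3 at -0.36 ± 0.12. Glucocorticoid response genes fell (9 of 10 lower, mean -0.22, adjusted p = 9.93e-05), with Cdkn1a at -0.50 ± 0.12 and Sgk1 at -0.39 ± 0.24. Each of these lists had adjusted p = 0.401 with an estimated correlation. Myelin genes rose (15 of 15 higher, mean 0.29, adjusted p = 1.02e-05), with Ermn at 0.45 ± 0.22, while oxidative phosphorylation (19 of 19 lower, mean -0.13, adjusted p = 1.27e-04) and ribosomal protein genes (23 of 24 lower, mean -0.12, adjusted p = 1.02e-05, Rpl13 at -0.31 ± 0.14) fell. All 3 had adjusted p = 0.784 with an estimated correlation. By edgeR 0 genes passed, 342 had an unadjusted p under 0.05, and DESeq2 gave 0 and 373. Beside Cdkn1a, the genes of smallest p were the synaptic pentraxin gene Nptx2 at -0.40 ± 0.13, Ypel2 at 0.26 ± 0.073 and the mitochondrial helicase gene Supv3l1 at 0.24 ± 0.068. Without sham vehicle replicate 2 the immediate early list kept its call at -0.21, the myelin list was at 0.12 (adjusted p = 0.0734) and the oxidative phosphorylation list at -0.060 (adjusted p = 0.0579), and without replicate 4 the latter was at -0.073 (adjusted p = 0.46) and the ribosomal list at -0.035 (adjusted p = 0.855). By permutation within cohorts no list passed for injury in males (smallest adjusted p = 0.167) or in females (0.877). In males only 162 arrangements of the labels exist, so no permutation p could lie under 0.00617. The glucocorticoid list reached that floor, and a single list could not pass after adjustment.

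The injury effect was then compared between the sexes (male minus female). Myelin genes had a higher male effect in 15 of 15 members (mean 0.43, adjusted p = 2.27e-05), with Ermn at 0.63 ± 0.28. Immediate early genes had a lower male effect in 13 of 14 (mean -0.44, adjusted p = 1.85e-04), with Egr4 at -1.19 ± 0.35 and Junb at -0.97 ± 0.46. Ribosomal protein genes had a lower male effect in 21 of 24 (mean -0.12, adjusted p = 0.00131, Rpl13 at -0.46 ± 0.18). None of these 3 lists passed with an estimated correlation (adjusted p = 0.89 each). No gene passed by edgeR, 591 had an unadjusted p under 0.05, and DESeq2 gave 0 and 622. The leading genes were the ubiquitin ligase gene Fbxo32 at 0.66 ± 0.18 (adjusted p = 0.786), Ift80 at 0.36 ± 0.095, the Notch-regulated gene Nrarp at -0.49 ± 0.13 and Ydjc at -0.65 ± 0.17. Limma voom with quality weights, chosen after seeing the data, called 8 genes. Without the 4 far libraries the myelin list was at 0.15 (adjusted p = 0.649) and the immediate early list at -0.32 (adjusted p = 0.136), while the ribosomal list kept its call at -0.21 (adjusted p = 1.68e-07). The ribosomal list did not pass without male sham vehicle replicate 2 (-0.069, adjusted p = 0.0965) or 4 (-0.033, adjusted p = 0.818).

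In injured mice, SB was compared with vehicle to find what the inhibitor changed in the late transcriptome. Oligodendrocyte and myelin genes fell: all 15 were lower, with a mean log2 fold change of -0.33 (adjusted p = 6.63e-21), and 14 passed when adjusted over the list alone, against 0 over all genes. The myelin protein gene Mobp was at -0.41 ± 0.14, Mog at -0.38 ± 0.12 and Opalin at -0.38 ± 0.12. Mobp stood at 977 ± 302 CPM (SD, n = 19) with SB and 1281 ± 328 CPM (SD, n = 20) with vehicle, beside 1345 ± 713 CPM (SD, n = 14) in sham vehicle mice. With an estimated correlation, which was high for this list, the adjusted p was 0.171. Genes of oligodendrocyte precursors and the wider lineage fell as well (5 of 6 lower, mean -0.16, adjusted p = 0.00161; adjusted p = 0.455 with an estimated correlation), with Bcas1 at -0.35 ± 0.12 and the lineage transcription factor gene Olig2 at -0.19 ± 0.083.

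Layer and vessel genes moved in the same comparison. Upper cortical layer genes rose, 7 of 7 higher (mean 0.14, adjusted p = 0.00304), with the layer transcription factor genes Cux2 at 0.27 ± 0.079 and Cux1 at 0.16 ± 0.068, whereas deep layer genes fell (7 of 9 lower, mean -0.070, adjusted p = 0.0421), with Etv1 at -0.17 ± 0.096 and Cplx3 at -0.15 ± 0.076. Endothelial genes rose (9 of 9 higher, mean 0.096, adjusted p = 0.0073), with the von Willebrand factor gene Vwf at 0.25 ± 0.11 and Pecam1 at 0.10 ± 0.065. Striatal genes rose (5 of 5 higher, mean 0.28, adjusted p = 0.0421), with Ppp1r1b, which encodes a dopamine-regulated phosphatase inhibitor, at 0.31 ± 0.15. Ribosomal protein genes fell, 24 of 24 lower (mean -0.072, adjusted p = 1.35e-06). With an estimated correlation the upper layer, deep layer, endothelial, striatal and ribosomal lists each had adjusted p = 0.455. Oxidative phosphorylation genes fell (19 of 19 lower, mean -0.049, adjusted p = 0.0154, Ndufb3 at -0.11 ± 0.057), with adjusted p = 0.635 with an estimated correlation.

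**Figure D2:**
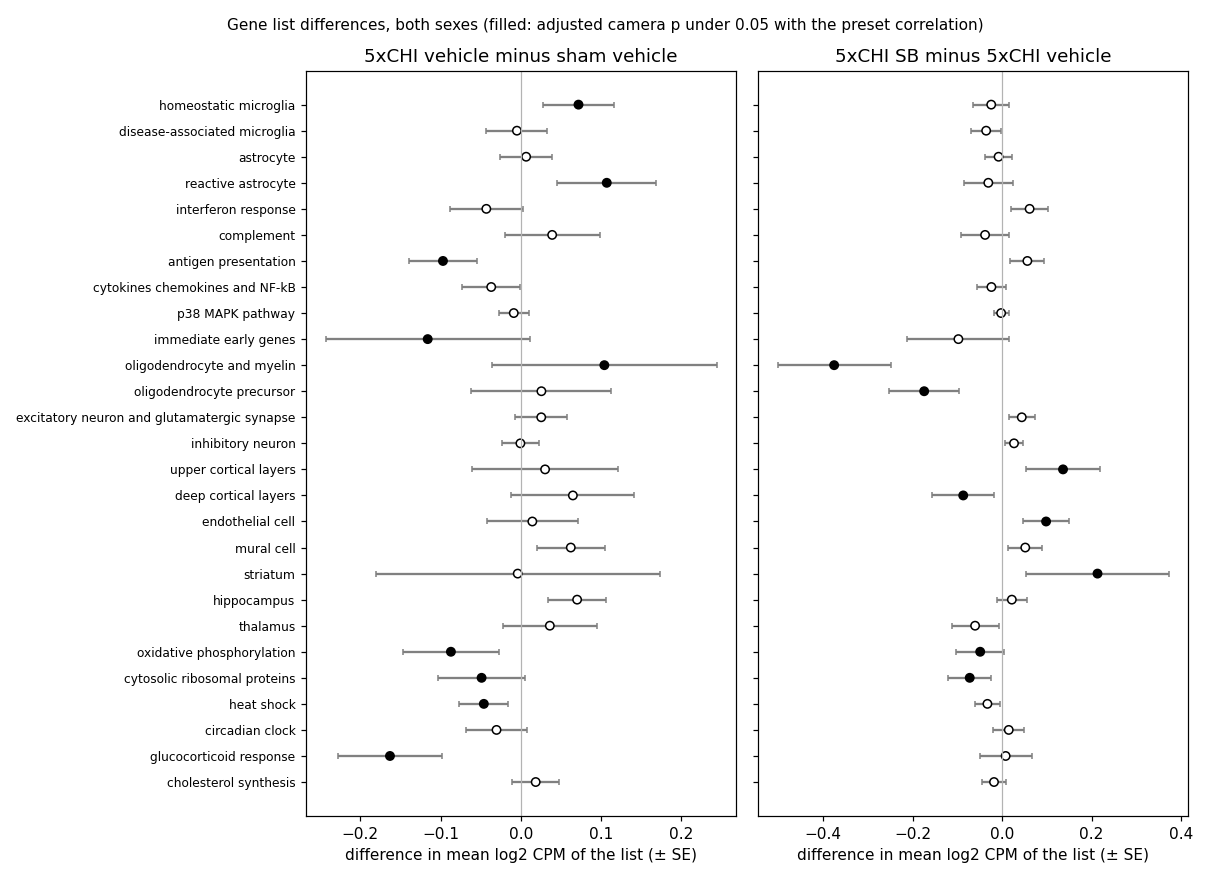
Difference in mean log2 CPM (± SE) for each of the 27 tested lists, for injury in vehicle mice at left and SB in injured mice at right, both sexes. Filled points mark lists with adjusted p under 0.05 by camera with the preset correlation, 9 for injury and 8 for SB, and the myelin list lies farthest from 0 under SB.

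No single gene passed for SB by edgeR or DESeq2, whereas limma voom with quality weights, chosen after seeing the data, called 1. By edgeR 0 of 9636 genes had an adjusted p under 0.05 (smallest 0.655), 680 had an unadjusted p under 0.05 against 481.8 by chance among independent genes, and DESeq2 gave 0 and 705. Lower with SB, without passing, were Dbndd2 (-0.23 ± 0.059, unadjusted p = 3.46e-04), the axon outgrowth gene Shtn1 (-0.23 ± 0.063), the neuronal transcription factor gene Neurod6 (-0.21 ± 0.058), Cnih4 (-0.12 ± 0.035) and Qdpr, a pterin-recycling enzyme gene (-0.28 ± 0.080). Dbndd2, Shtn1 and Qdpr were also high in a myelin-rich library, female sham vehicle replicate 1. Whether they moved apart from the myelin genes was not tested. Higher were the laminin gene Lamb2 (0.20 ± 0.057), the potassium channel gene Kcnh4 (0.28 ± 0.079), Zic1 (0.42 ± 0.12), Cux2 and the fibronectin gene Fn1 (0.31 ± 0.089). Fn1 stood at 84.5 ± 27.5 CPM (SD, n = 19) with SB and 67.4 ± 20.1 CPM (SD, n = 20) with vehicle. The 95% interval lay within 1.5-fold in either direction for 99.7% of genes. Neither Mapk14 (0.040 ± 0.031), Mapk11 (0.053 ± 0.071) nor Mapkapk2 (0.0043 ± 0.048), all of the pathway SB inhibits at the protein level, passed, and the p38 list was not called (adjusted p = 0.582). Gfap was at -0.16 ± 0.087 (unadjusted p = 0.0754).

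The other 18 lists without a call for SB, of which the immune lists had few measured members, had adjusted p from 0.0589 to 0.954. They included the excitatory neuron list, of which 15 of 18 genes were higher. Counted in either direction, 2 of its genes passed when adjusted over the list alone, and its member Neurod6 was lower. The others were disease-associated microglia, homeostatic microglia, astrocyte, reactive astrocyte, interferon response, complement, antigen presentation, cytokine and NF-kB, immediate early, inhibitory neuron, mural cell, hippocampus, thalamus, heat shock, circadian clock, glucocorticoid response and cholesterol synthesis genes. Within cohorts the myelin score of injured SB mice differed by -0.38 on average and was higher in 1 of the 8 cohorts, the differences running from -1.33 to 0.17. The permutation test within cohorts, added after the list results were seen, gave p = 0.00298 for it, or 0.0805 after adjustment over the 27 lists, and no list passed. Without the 4 far libraries the myelin list was at -0.28 (adjusted p = 4.38e-19), and the deep layer list (-0.036, adjusted p = 0.299) and the striatal list (0.25, adjusted p = 0.0894) no longer passed. The striatal rise rested on male injured SB replicate 1, without which it was at 0.089 (adjusted p = 0.434), and the deep layer call was lost in 14 of the 58 removals of a single library. With the myelin level as a term, chosen after seeing the data, the upper layer list turned to -0.017 (adjusted p = 0.947), the deep layer list to 0.050 (adjusted p = 0.704) and the precursor list to 0.034 (adjusted p = 0.713). With 2 surrogate variables the oxidative phosphorylation list turned to 0.0046 (adjusted p = 0.797), and the striatal (0.25, adjusted p = 0.0892) and ribosomal lists (-0.023, adjusted p = 0.0875) did not pass. With the slope over transcript length as a term, also added after seeing the data, the oxidative phosphorylation list was at 0.010 and the ribosomal list at -0.021 (adjusted p = 0.12).

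In females SB was followed by lower myelin genes, which fell in 15 of 15 members (mean -0.30, adjusted p = 3.29e-10), with Mobp at -0.42 ± 0.18. Without the 4 far libraries, of which injured SB replicate 8 belongs to this comparison, the list was at -0.20 and kept its call (adjusted p = 1.83e-05 by camera). The measured genes of the disease-associated microglia list fell (9 of 11 lower, mean -0.078, adjusted p = 0.0174), with the ferritin gene Fth1 at -0.20 ± 0.077 and the tetraspanin gene Cd9 at -0.23 ± 0.098. Only 11 of its 22 listed genes were measured, Cd68 not among them, so a change in microglial state cannot be read from it. Oxidative phosphorylation (19 of 19 lower, mean -0.13, adjusted p = 2.53e-07, Ndufb3 at -0.21 ± 0.074) and ribosomal protein genes (24 of 24 lower, mean -0.13, adjusted p = 2.86e-11, Rpl37 at -0.19 ± 0.069) fell. All 4 had adjusted p = 0.655 with an estimated correlation. By edgeR 0 genes passed, 695 had an unadjusted p under 0.05, and DESeq2 gave 0 and 728. The leading genes were Nudt19 at -0.25 ± 0.063 (adjusted p = 0.693), Tmem199 at -0.18 ± 0.051, the receptor-like gene Ptk7 at 0.34 ± 0.10 and the transcriptional regulator gene Rai1 at 0.30 ± 0.086. The disease-associated microglia, oxidative phosphorylation and ribosomal lists did not pass with the length slope as a term (adjusted p = 0.394, 0.461 and 0.0554). The call of the disease-associated microglia list was also lost without injured SB replicate 7 (-0.063, adjusted p = 0.0731) and with the myelin level as a term (-0.070, adjusted p = 0.201).

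In males myelin genes fell with SB in 15 of 15 members (mean -0.37, adjusted p = 7.07e-21), with Opalin at -0.40 ± 0.18, together with the precursor list (6 of 6 lower, mean -0.21, adjusted p = 7.4e-05). Striatal genes rose (5 of 5 higher, mean 0.52, adjusted p = 1.06e-04, Ppp1r1b at 0.57 ± 0.23), and so did interferon response genes (5 of 6 higher, mean 0.16, adjusted p = 0.0128), with Lgals3bp at 0.46 ± 0.16 and the signalling gene Stat2 at 0.20 ± 0.095. Thalamic genes fell (4 of 4 lower, mean -0.14, adjusted p = 0.0464). These 5 lists had adjusted p = 0.134 with an estimated correlation. Upper layer genes rose (7 of 7 higher, mean 0.17, adjusted p = 4.48e-04, Cux2 at 0.29 ± 0.12) and immediate early genes fell (13 of 14 lower, mean -0.20, adjusted p = 3.62e-05, Egr1 at -0.34 ± 0.15), both with adjusted p = 0.203 with an estimated correlation. Endothelial genes rose (8 of 9 higher, mean 0.11, adjusted p = 0.00506; adjusted p = 0.275 with an estimated correlation). Gene by gene, edgeR called 0, 181 had an unadjusted p under 0.05, and DESeq2 gave 0 and 197. At the head of the ranking were Slc16a6 at 0.39 ± 0.12 (adjusted p = 1), Kcnh4 at 0.37 ± 0.12, Srbd1 at -0.22 ± 0.067 and the cap-binding gene Eif4e2 at -0.13 ± 0.043. Single injured SB males carried some of these calls. Without replicate 1 the striatal list was at 0.14 (adjusted p = 0.255), without replicate 5 the interferon list was at 0.078 (adjusted p = 0.336), and without replicate 8 the myelin list was at -0.25 and kept its call. By permutation within cohorts no list passed for SB in males (smallest adjusted p = 0.292) or in females (0.211). The thalamic call was lost in 19 of the 58 removals of a single library. With the myelin level as a term the precursor list was at 0.0071 and the upper layer list at -0.0019 (adjusted p = 0.962 for both), and the interferon list did not pass (0.13, adjusted p = 0.142).

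The SB effect in injured mice was compared between the sexes (male minus female). Striatal genes had a higher male effect in 5 of 5 members (mean 0.48, adjusted p = 0.00319, Ppp1r1b at 0.53 ± 0.30), and oxidative phosphorylation genes in 19 of 19 (mean 0.15, adjusted p = 6.91e-09, Ndufa5 at 0.25 ± 0.13), each with adjusted p = 0.449 with an estimated correlation. Ribosomal protein genes had a higher male effect in 24 of 24 (mean 0.11, adjusted p = 1.09e-07, Rpl37 at 0.25 ± 0.11; adjusted p = 0.456 with an estimated correlation). Immediate early genes had a lower male effect in 13 of 14 (mean -0.31, adjusted p = 1.1e-07, Egr1 at -0.48 ± 0.20; adjusted p = 0.447 with an estimated correlation). No gene passed by edgeR, 88 had an unadjusted p under 0.05, and DESeq2 gave 0 and 90. Leading genes were Nlrx1, a mitochondrial immune regulator gene, at 0.41 ± 0.12 (adjusted p = 1), Tmem192 at 0.33 ± 0.11, Shisal1 at -0.32 ± 0.12 and Etv3 at -0.27 ± 0.083. The striatal difference rested on male injured SB replicate 1, without which it was at 0.094 (adjusted p = 0.446), and it did not pass without male injured vehicle replicate 5 (0.33, adjusted p = 0.0773). The ribosomal list did not pass with the length slope as a term (0.025, adjusted p = 0.326). The myelin list was not among the 4 called here.

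Injured SB mice were next compared with sham vehicle mice, to see what separated treated injured cortex from uninjured cortex. Myelin genes fell in 15 of 15 members (mean -0.26, adjusted p = 3.58e-07), with Mobp at -0.38 ± 0.15. Glucocorticoid response genes fell (8 of 10 lower, mean -0.17, adjusted p = 3.16e-04), with Sgk1 at -0.46 ± 0.15, Cdkn1a at -0.26 ± 0.080 and Tsc22d3 at -0.25 ± 0.078. Immediate early genes fell (11 of 14 lower, mean -0.18, adjusted p = 0.00145, Bdnf at -0.27 ± 0.087). Their mean log2 CPM was lower only in males (5.91 in injured SB, 6.46 in sham vehicle) and was higher in females (6.47 and 6.33). Upper layer (6 of 7 higher, mean 0.14, adjusted p = 0.0121, Cux2 at 0.27 ± 0.089), excitatory neuron (13 of 18 higher, mean 0.058, adjusted p = 0.0157, Camk2a at 0.18 ± 0.070 and Shank3 at 0.20 ± 0.080) and endothelial genes (8 of 9 higher, mean 0.10, adjusted p = 0.0188, Cdh5 at 0.16 ± 0.077) rose. With an estimated correlation these 6 lists had adjusted p = 0.418 except glucocorticoid response, at 0.398. By permutation within cohorts no list passed in this comparison (smallest adjusted p = 0.192), and the myelin list had p = 0.0984, or 0.266 after adjustment.

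Oxidative phosphorylation genes fell in this comparison, 19 of 19 lower (mean -0.15, adjusted p = 1.2e-08), with the cytochrome oxidase gene Cox4i1 at -0.18 ± 0.061. Ribosomal protein genes fell, 24 of 24 lower (mean -0.14, adjusted p = 1.48e-10), and so did heat shock genes, 10 of 10 lower (mean -0.082, adjusted p = 0.00145, the mitochondrial chaperonin gene Hspe1 at -0.20 ± 0.061). Mural cell genes rose (3 of 3 higher, mean 0.11, adjusted p = 0.0381, the pericyte receptor gene Pdgfrb at 0.21 ± 0.064). These 4 lists had adjusted p = 0.398 with an estimated correlation. Precursor genes fell (5 of 6 lower, mean -0.16, adjusted p = 0.0323, Bcas1 at -0.34 ± 0.13; adjusted p = 0.462 with an estimated correlation). By edgeR 0 genes passed (smallest adjusted p = 0.329), 1211 had an unadjusted p under 0.05, and DESeq2 gave 0 and 1271. The leading genes were the cytochrome oxidase gene Cox7a2 at -0.23 ± 0.063, Dbndd2 at -0.25 ± 0.066, Rnf145 at 0.13 ± 0.034 and the cilia gene Wdr19 at 0.22 ± 0.054. Without male sham vehicle replicate 5 the upper layer list was at 0.11 (adjusted p = 0.1), the endothelial list at 0.097 (adjusted p = 0.0904) and the mural list at 0.10 (adjusted p = 0.143). Of the 58 removals of a single library, 13 ended the mural call and 11 the precursor call, and the excitatory list did not pass without male sham vehicle replicate 4 (0.028, adjusted p = 0.148) or female sham vehicle replicate 1 (0.037, adjusted p = 0.0863). Without the 4 far libraries the oxidative phosphorylation (-0.036, adjusted p = 0.112), ribosomal (-0.034, adjusted p = 0.0952), immediate early (-0.067, adjusted p = 0.112) and excitatory lists (0.025, adjusted p = 0.181) lost their calls. Fold change followed transcript length across 9549 genes (Spearman rho 0.587), and with the length slope as a term the oxidative phosphorylation and ribosomal lists were at -0.0086 and -0.011 (adjusted p = 0.579 and 0.483).

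In sham mice SB was compared with vehicle to see the inhibitor without injury, with 5 SB and 14 vehicle mice. Excitatory neuron and synapse genes rose (14 of 18 higher, mean 0.081, adjusted p = 0.0103), with the kinase gene Camk2a at 0.20 ± 0.11. Oxidative phosphorylation (18 of 19 lower, mean -0.14, adjusted p = 2.95e-04, Ndufa5 at -0.25 ± 0.11) and ribosomal protein genes (24 of 24 lower, mean -0.13, adjusted p = 1.19e-05, Rps3 at -0.21 ± 0.090) fell. All 3 had adjusted p = 0.89 with an estimated correlation. By edgeR 0 genes passed (smallest adjusted p = 0.677), 676 had an unadjusted p under 0.05, and DESeq2 gave 0 and 703. The leading genes were the mediator subunit gene Med10 at -0.28 ± 0.068, Utp11 at -0.29 ± 0.078, the growth kinase gene Mtor at 0.25 ± 0.082 and Tm9sf4 at 0.17 ± 0.057. Mapk11 was at -0.25 ± 0.13 (unadjusted p = 0.0505), Mapk14 at 0.023 ± 0.053, Mapkapk2 at 0.010 ± 0.084 and Gfap at 0.043 ± 0.15. Without female sham SB replicate 1 the oxidative phosphorylation and ribosomal lists were at -0.091 and -0.077 (adjusted p = 0.0578 for both), and the excitatory list did not pass without male sham SB replicate 2 (0.039, adjusted p = 0.16) or male sham vehicle replicate 4 (0.041, adjusted p = 0.0932). No list passed by permutation within cohorts (smallest adjusted p = 0.564). That test has only 48 arrangements of the labels here, too few for a single list to pass after adjustment, so it decides nothing. All 3 calls were lost without the far libraries, at 0.045, -0.043 and -0.044 (adjusted p = 0.372, 0.463 and 0.385). With 2 surrogate variables the oxidative phosphorylation and ribosomal lists passed in the opposite direction (0.044 and 0.041, adjusted p = 0.0045 and 6.33e-04), and the excitatory list was at 0.0065 (adjusted p = 0.693).

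The injury by SB interaction asked whether the SB effect differed between injured and sham mice. The SB effect on myelin genes was lower in injured than in sham mice in 15 of 15 members (mean -0.18, adjusted p = 0.00116; adjusted p = 0.67 with an estimated correlation). It was higher in injured mice for antigen presentation genes (3 of 3, mean 0.22, adjusted p = 0.0185, Tap2 at 0.36 ± 0.17; adjusted p = 0.0626 with an estimated correlation) and for oxidative phosphorylation genes (17 of 19, mean 0.094, adjusted p = 0.0284, Ndufa5 at 0.18 ± 0.13; adjusted p = 0.718 with an estimated correlation). By edgeR 0 genes passed, 133 had an unadjusted p under 0.05, and DESeq2 gave 0 and 144. The leading genes were Cdc26 at 0.26 ± 0.081 (adjusted p = 0.999), Med10 at 0.25 ± 0.078, Gnpda1 at -0.22 ± 0.075 and Trim45 at -0.32 ± 0.11. The oxidative phosphorylation call ended in 11 of the 58 removals of a single library, among them female sham SB replicate 1 (0.040, adjusted p = 0.449), and with no cohort term (0.078, adjusted p = 0.182). Without the far libraries it was at -0.0050 (adjusted p = 0.718) and the antigen presentation list at 0.16 (adjusted p = 0.194), and with 2 surrogate variables the oxidative phosphorylation list passed in the opposite direction (-0.040, adjusted p = 0.0447).

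Whether SB changes opposed injury changes across genes was measured as the covariance of both sets of log2 fold changes over 9636 genes, which are not independent replicates. Both comparisons use the injured vehicle mice, and that alone gives a negative value: with those mice shared the covariance was -0.00025 (r -0.064), against -0.0018 (r -0.44) in simulated groups without effects. With the injured vehicle mice halved at random within cohorts, so that each comparison had its own, the mean covariance over 50 halvings was 9.38e-04 ± 4.69e-04 (SD over halvings), with r 0.15. Simulated groups without effects gave 5.12e-06. Among 50 shuffles of the labels within cohorts the halved value ranged from -0.0041 to 0.0046, and 31 lay at or below the observed one, so no opposition was detected beyond the spread of shuffled labels. As no gene passed for injury, no share of injury genes with the opposite SB change was computed. The glucocorticoid response genes, lowest for injury, were at a mean of 0.0062 under SB (4 of 10 higher, adjusted p = 0.954).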

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

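Of the tests below, those of white matter, of SB without injury, of single libraries in each sex, of the 4 far libraries and of the length and myelin terms were chosen only after the results were seen, and the patterns weighed were picked from the list results. Of 260 sets of values from groups of 4 to 10 libraries, 31 held a library that stood apart from its group by Dixon's test, where chance gives about 13. They came from 12 libraries. The injured female groups (11 and 12 libraries) and the sham SB groups (3 and 2) were outside this range and were not examined.

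Female sham vehicle replicate 1 gave 13 of them and looked rich in myelin and poor in upper layer genes. Its myelin list stood at 8.77 log2 CPM, against 6.88 to 7.75 in the other libraries of its group, and its upper layer list at 5.76. In CPM it held Mobp at 3350 (others 865.1 to 1823), Bcas1 at 756.8, Qdpr at 568.7, Gfap at 275.1, Mog at 149.2, Dbndd2 at 149.2, Shtn1 at 113.5, Opalin at 74.1, Olig2 at 54.38, Aspa at 45.84 and Cplx3 at 35.6. Male sham vehicle replicate 2 stood apart for upper layer genes (7.12 log2 CPM), deep layer genes (4.77), Ppp1r1b (92.72 CPM) and Aspa (8.81 CPM). Striatal genes set other males apart: injured SB replicate 1 for Ppp1r1b (381.7 CPM, others 63.1 to 159.1), and injured vehicle replicate 6 for the striatal list (6.57 log2 CPM). This is not a trait of males alone. In the unexamined female groups, injured SB replicate 9 (7.02 log2 CPM) and injured vehicle replicate 8 (6.66) were the highest of their groups on that list.

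Other males stood apart for stress and activity genes. Injured SB replicate 5 had Cdkn1a at 27.21 CPM and the glucocorticoid list at 5.69 log2 CPM, and injured vehicle replicate 8 had Sgk1 at 114.1 CPM (others 53.97 to 71.35), Cux2 at 201 CPM and the oxidative phosphorylation list at 6.20 log2 CPM. Injured vehicle replicate 1 had the immediate early list at 6.77 log2 CPM and Egr3 at 257.4 CPM, while sham vehicle replicate 4 had Egr3 at 150.7 CPM. Single values were Kcnh4 at 43.22 CPM in injured SB replicate 3, Mapkapk2 at 26.36 CPM in injured vehicle replicate 7 and Cx3cr1 at 46.33 CPM in sham vehicle replicate 5. In females, sham vehicle replicate 7 had B2m at 109.5 CPM.

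List effects differed between groups in 10 cases, over 6 lists, by camera with the preset correlation, and none of the 10 passed with an estimated one. Between SB effects in injured and sham mice these were antigen presentation (0.22), myelin (-0.18) and oxidative phosphorylation (0.094). Between male and female injury effects they were immediate early (-0.44), myelin (0.43) and ribosomal protein genes (-0.12). Between male and female SB effects they were immediate early (-0.31), striatal (0.48), oxidative phosphorylation (0.15) and ribosomal protein genes (0.11).

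The first pattern weighed is the lower glucocorticoid response list of injured vehicle mice (list score difference -0.16 ± 0.064 SE, permutation p = 0.0132). Removal of the part that followed the first component of the clock genes left -0.147 (91.8% of it, permutation p = 0.0151), and removal of the immediate early list left -0.156 (97.2%, permutation p = 0.0136), which argues against time of day or activity at sacrifice as the whole cause, as far as those genes record them. A single deviating library is argued against as the whole cause in males, whose difference (-0.213, permutation p = 0.00617) was still -0.182 (85.8% of it, permutation p = 0.037) in the removal that shrank it most. In females (-0.108, permutation p = 0.314) it fell to -0.0258 without female sham vehicle replicate 1, so that library could account for most of the female part. Over both sexes -0.119 remained without it (74.3%, permutation p = 0.0619) and -0.163 without the 4 far libraries, of which it is one (permutation p = 0.00629), so its share in the whole pattern stays open. A lasting effect of injury on stress hormone signalling is a hypothesis, and hormone levels were not measured here. The score does not pass after adjustment over the 27 lists (adjusted p = 0.237).

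The second is the lower myelin list of injured SB mice (-0.378 ± 0.126 SE, permutation p = 0.00298). Injured SB replicate 8 was the lowest of its group in females (6.13 log2 CPM, group mean 7.12) and in males (6.01, group mean 7.18). Permutation was not repeated without these libraries, so their share in the pattern stays open. Libraries with more upper and fewer deep layer genes had less myelin within groups (r -0.713 across the 58 libraries), and after removal of that layer score the difference was -0.23 ± 0.0881 (60.9% of it, permutation p = 0.0205), so the depth of the dissected piece could account for part of it and stays open. White matter in the piece stays open too, as deep layer genes differed by -0.0917 (permutation p = 0.185). An action of SB on oligodendrocytes without injury cannot be told apart from none with 5 sham SB mice, at -0.167 (permutation p = 0.71). That value and its sign rest on cohort F2 (-1.16), whose only sham vehicle library is the myelin-rich replicate 1, beside 0.252 in F1, -0.109 in M1 and -0.122 in M2. No test here separates a change in oligodendrocytes from a change in what was dissected.

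The third is the joint fall of oxidative phosphorylation and ribosomal protein genes in injured SB against sham vehicle mice (-0.131 ± 0.056 SE), which the permutation test did not pass even before adjustment (p = 0.0514). Genes outside these lists matched on transcript length, GC content and level differed by -0.0946 (72.2% of it, permutation p = 0.0227), and the lists differed from their matches by -0.0363 (permutation p = 0.208), so a trend over transcript length is consistent with most of the pattern. The lists have a median length of 1020 bases and their matches 1221, against 3726 for all genes. Without the 4 far libraries the calls of both lists were lost (-0.036 and -0.034, adjusted p = 0.112 and 0.0952 by camera). Library depth is argued against, since removal of the part that followed the total left -0.133 (permutation p = 0.0394). Whether the length trend comes from RNA quality, library preparation or the tissue was not tested.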

How the results depend on the processing

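Tests with limma voom, without the far libraries, without single libraries of the larger groups, with the myelin level and with the length slope were chosen only after the results were seen. The absence of single genes past the threshold held with edgeR under every alternative, with DESeq2 and with each of the 58 libraries left out. Limma voom with quality weights, chosen after seeing the data, called 1 gene for SB in injured mice (Myo16, named after its values were seen; adjusted p = 0.0192) and 8 for the sex difference of the injury effect (smallest adjusted p = 0.049), and the cause was not tested. No filter and a mean CPM of at least 1 removed no gene and say nothing about stability. The opposition covariance lay between 8.87e-04 and 9.38e-04.

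Numbers of called lists moved more. For injury, 9 became 1 with an estimated correlation, and 6 (without male sham vehicle replicate 4) to 12 (without female sham vehicle replicate 1) with a library left out. For SB, 8 became 0 with an estimated correlation, 5 with 2 surrogate variables, 3 with the myelin level and 5 with the length slope, and 6 to 10 with a library left out. Lists were not tested with DESeq2, limma voom or each sex alone, nor the myelin list with the myelin level. Permutation of list scores was not counted as a setting. Of 64 calls over all comparisons, 14 kept their direction and call in every setting tested for them but the estimated correlation. With that correlation 1 did, the glucocorticoid list for injury (-0.203 to -0.14 with a library left out). Over lists and settings, 4016 values kept their direction and call, 306 lost the call and 21 turned. Of the 4016, 3545 came from removals of 1 library, among them libraries outside the comparison. No filter and the mean CPM rule gave 64 each without removing a gene. Of the 64 calls, 38 were kept without the far libraries and 41 with the length slope. Single genes kept their direction in 9898 cases and turned in 26. None of them passed in the main test, so staying short of the threshold says little.

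With the length slope, oxidative phosphorylation turned to 0.0133 for injury in males, 0.0102 for SB, 0.0135 for SB in sham mice and -0.00329 for the interaction, and ribosomal genes to 0.00996 for injury, 0.004 for injury in males and 0.00466 for SB in sham mice. Without the far libraries, oxidative phosphorylation turned to 0.0124 for injury, 0.0845 for injury in females (adjusted p = 0.0416) and -0.00498 for the interaction, ribosomal genes to 0.0354 for injury (adjusted p = 6.17e-04), Rps3 to 0.00755 and Mapkapk2 under SB to -0.00529. With 2 surrogate variables, oxidative phosphorylation turned to 0.00464 for SB, 0.0444 for SB in sham mice (adjusted p = 0.0045) and -0.0398 for the interaction (adjusted p = 0.0447), ribosomal genes to 0.0414 for SB in sham mice (adjusted p = 6.33e-04), Ndufa5 there to 0.0151 and Mapkapk2 under SB to -0.00522. With the myelin level, SB values turned for precursor (0.0338, males 0.00707), upper layer (-0.0174, males -0.00188) and deep layer genes (0.0504), Cplx3 (0.00132), Mapk11 (-0.0224) and Mapkapk2 (-0.00248). The myelin list itself has no value there, as the term is made from it. Limma voom put Rps3 for injury at 0.0317. With a library left out, the myelin list for injury ran from -0.0116 to 0.144 and Mapkapk2 from -0.0121 to 0.0169 for SB and from -0.023 to 0.0302 for SB in sham mice. The causes of these turns were not tested.

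The replicate block in place of the cohort called 0 genes in every comparison (71 with an unadjusted p under 0.05 for injury, 504 for SB), and 10 and 7 lists. Libraries of the same number correlated with a median r of -0.0805 in females (12 of 38 pairs over 0.1) and 0.0489 in males (9 of 24). Pairs of other numbers gave 0.0108 in females (143 of 397) and -0.0239 in males (52 of 162). These values show no clear pairing but cannot exclude one, and the labels do not say. The numbers were read as names. The table holds no gene under a mean count of 270.1, so rare transcripts are outside what it can show.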

Other observations

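Among the tests below, the splits that count genes for injury (both sexes, each sex and their difference) and the checks of length were chosen only after the results were seen. Cohorts differed in daily rhythm and activity genes. The fifth principal component (5.1% of the variance) followed the cohort for 78%, with the clock output genes Ciart, Dbp and Bhlhe41 at one end and the activity genes Egr3, Nptx2, Homer1, Arc and Bdnf at the other, genes listed by their weight on the component after it was computed. Each cohort is of 1 sex, so this share includes the 25.6% that followed sex. Cohort F4 lay lowest on the first component (-17.9 ± 4.08 SD, 5 mice) and cohort M2 highest (9.49 ± 5.06 SD, 6 mice), and F4 also had the lowest mean total (31200000 ± 1890000 counts, SD). The sixth component (3.44%), with Fos, Arc, Junb, Nr4a1 and Npas4 at one end, followed the condition beyond the cohort for 20% and the cohort for 14.1%, shares without a computed chance level.

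Transcript length ordered the fold changes of most comparisons. Across 9549 genes, which are not independent replicates, Spearman's rho of fold change and length was 0.491 for injury, 0.366 for SB, 0.587 for injured SB against sham vehicle, 0.516 for SB in sham mice and -0.366 for the interaction. By sex it was 0.0217 for injury in females and 0.484 in males, and 0.492 for SB in females and 0.076 in males, a difference that was not tested. The loadings of components 1 and 3 followed length (0.525 and 0.566), those of component 4 ran against it (-0.232) and those of component 2 did not follow it (-0.00231). Measured per library, the slope over length did not differ between groups by a permutation test within cohorts (p = 0.273 for injury, 0.139 for SB, 0.0635 for injured SB against sham vehicle and 0.417 for SB in sham mice).

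Other splits of the samples within cohorts could give results as large as the real ones, so chance cannot be excluded for any count. The numbers below count the real split itself among the 100 or 48. Counting genes with an unadjusted p under 0.05, 71 of 100 splits reached the 169 of injury (highest other 1431), 65 the 303 of injury in females (2069) and 37 the 342 in males (1365). For SB in injured mice, 9 of 100 reached 680 (highest other 1689), 17 the 695 in females (1349) and 32 the 181 in males (726). For injured SB against sham vehicle 10 of 100 reached 1211 (highest other 2772), for SB in sham mice 13 of 48 reached 676 (1566), for the interaction 87 of 100 reached 133 (2042), and for the sex differences of injury and SB 21 and 81 of 100 reached 591 and 88 (1831 and 1676). In 4 of the other splits for injured SB against sham vehicle genes were called, up to 573 in a split, which points to a structure of the samples. Still, 4 such splits are no more than the threshold allows, and no test was made for a structure.

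Called lists gave the same answer. With the preset correlation the other splits called a median of 3 to 5 lists, depending on the comparison. The adjusted p-values of camera with that correlation therefore overstate the evidence in these samples. With an estimated correlation 1 of the 64 calls was kept, and the splits were not repeated with it. The real split is again counted in, so the 5 of 100 for injured SB against sham vehicle lies at the limit. For injury 9 of 100 splits called the 9 lists of the real split or more (highest other 12), for injury in females 49 called 6 (11) and in males 45 called 5 (10). For SB 20 of 100 called 8 or more (highest other 13), in females 57 called 4 (11) and in males 17 called 8 (12). For injured SB against sham vehicle 5 of 100 called 11 or more (14), for SB in sham mice 33 of 48 called 3 (9), for the interaction 74 of 100 called 3 (11), and for the sex differences of injury and SB 77 called 3 (12) and 74 called 4 (11).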
